A study of Mus musculus with 29 samples.

How the data were processed

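RNA sequencing read counts were analysed from 29 libraries of CD45-negative cells sorted from mouse tumors, made with a stranded total RNA kit. The deposited file holds raw read counts per Ensembl gene, one column per library, with no normalization, and the authors did not pool replicates. Whole numbers and unequal column totals in the file were checked to bear out the unit. Per the labels, the authors used CASAVA, cutadapt 1.9, Bowtie2 2.2.4, STAR 2.4.0k, SAMtools and Subread 1.4.6 with the mouse builds GRCm38 and mm10; the role of each tool, the strand setting and the annotation release are not stated. Gene symbols, positions and GC content were taken from the GENCODE annotation of GRCm38, and 810 identifiers without a symbol held 0.102% of counts.

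Samples were grouped by their titles into 9 groups. The STAT1 knockouts have 2 forms of title and were kept apart as set A (2 libraries, compared with 499 cas9) and set B (4 libraries, compared with the CRISPR control). The groupings, comparisons, gene lists, tests and the alternatives not named below as later were chosen before the data were examined. The labels name no batch. The 11 libraries of untreated and treated B16, 499 cas9 and set A were deeper (4167400 to 6564400 counts) than the 18 others (1871800 to 3644700), so a difference of batch between these sets cannot be told apart from depth, and 499 cas9 and the CRISPR control fall on opposite sides.

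Counts were modelled in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr (12520 of 48034), normalised by TMM and fitted in 1 robust quasi-likelihood model with a mean per group over all 29 libraries (20 residual degrees of freedom). Each of 11 comparisons was tested 2-sided with the quasi-likelihood F test, and genes with a Benjamini-Hochberg adjusted p under 0.05 within the comparison were called. The SE is the absolute log2 fold change divided by the square root of F. CPM values use TMM-normalised library sizes, except those of Gm42418 and the summed cell type markers, which use total counts per library. Gene lists (21 lists, 14 of them with at least 3 measured members) were tested with camera at a preset inter-gene correlation of 0.01, with the correlation estimated, and with fry (limma 3.58.1), adjusted over the lists of a comparison. Of 154 list and comparison pairs, 94 passed camera with the preset correlation, 45 with the estimated correlation and 85 passed fry. List counts are given over all genes tested and adjusted over the list alone. Fry tests whether the genes of a list move, on balance, in a direction, and does not compare the list with other genes.

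Named genes were chosen by a fixed rule: the targeted genes; in each comparison the 8 largest rises and 8 largest falls among called genes with a mean of at least 50 counts in the higher group and no overlap between the groups' libraries, without predicted or clone-named genes; and from each list up to 5 members with the smallest p, together with a fixed set of checkpoint, presentation, interferon and pigment genes. Not every gene that the rule picks is printed, with preference for those whose call does not rest on 1 library. A ratio against a group at 0 counts uses a floor of 3 counts over the group, and ratios with 1 to 3 counts carry an exact 95% interval. Gene families with close paralogs (H2 genes, guanylate-binding proteins, Oas1, Ifit3, Tgtp) share reads, so the split among their members is uncertain.

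The pipeline was tested on simulated data for each comparison, with 200 of 12520 genes changed. Of 100 genes changed by 2-fold, 61 to 76 were recovered over the 11 comparisons, and of 100 changed by 4-fold, 86 to 95, with 5 to 17 unchanged genes called. Overlaps between comparisons with shared controls were set beside simulated unchanged groups with the same controls. Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, a fit of the 2 compared groups alone, the replicate number as a block, the other 499 control, pooled STAT1 sets and leaving out each library. Removing each library's trend of expression on transcript GC content, the count against both controls and list counts without single libraries were added after the data were examined. Other splits of the libraries of a comparison into groups of the same sizes were fitted in the same way. All 29 columns were used and none were left out.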

Results

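Gene expression was measured by RNA sequencing in CD45-negative cells sorted from mouse tumors harvested on day 15. Tumors came from B16, a melanoma line, from B16 cells exposed to interferon-gamma (IFNy) in culture for weeks before injection, and from 499, a B16-derived line that resists immune checkpoint blockade. The 499 cells carried either cas9, a CRISPR control, or a knockout of STAT1, of the type I interferon receptor (IFNAR), of the type II interferon receptor (IFNGR) or of both receptors. The 29 libraries formed 9 groups. Total counts per library were 4167400 to 5341300 in 3 untreated B16 libraries, 4845500 to 5262800 in 3 IFNy-treated B16 libraries and 4546700 to 5747500 in 3 libraries of 499 with cas9. They were 5409300 to 6564400 in 2 STAT1 knockout libraries of a set called A here and 1988900 to 3644700 in 4 of a set called B, whose titles take a different form. The range was 2269100 to 2899700 in 3 CRISPR control libraries, 2826400 to 3242300 in 4 IFNGR knockouts, 1871800 to 2752800 in 4 IFNAR knockouts and 2696600 to 3280300 in 3 double receptor knockouts. Of 48034 genes counted, 12520 had enough reads to be tested. Expression is given below as CPM (normalised to library size, mean ± SD), and differences as log2 fold changes ± SE from edgeR with Benjamini-Hochberg adjusted p. The labels do not say whether replicates were separate animals, so the p-values measure spread between samples. The counts carry no molecular identifiers, so intervals and floors based on counts cover counting error only.

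The targeted genes were compared across the groups to place the labels beside the transcripts. Stat1 (ENSMUSG00000026104, chromosome 1, 52119440 to 52161865 on GRCm38), the transcription factor downstream of both receptors, measured 7.34 ± 1.39 CPM in STAT1 knockout set A (n = 2) and 7.98 ± 3.59 in set B (n = 4). It measured 76.2 ± 10.8 CPM in 499 with cas9 (n = 3) and 164 ± 55.0 in the CRISPR control (n = 3). Ifnar1 (ENSMUSG00000022967, chromosome 16, 91485238 to 91507441), a chain of the type I receptor, fell from 104 ± 23.3 CPM in the CRISPR control to 70.8 ± 7.05 in the IFNAR knockout (n = 4, log2 fold change -0.56 ± 0.12, adjusted p = 0.00224). Ifngr1 (ENSMUSG00000020009, chromosome 10, 19591949 to 19610229), a chain of the type II receptor, measured 13.8 ± 1.41 CPM in the IFNGR knockout (n = 4) against 17.7 ± 1.96 in the CRISPR control, a log2 fold change of -0.36 ± 0.18 that missed the threshold (adjusted p = 0.212). Against the IFNAR knockout, the IFNGR knockout had lower Ifngr1 (-0.88 ± 0.16, adjusted p = 0.00146) and higher Ifnar1 (0.55 ± 0.11, adjusted p = 0.0028). Small CRISPR deletions need not lower a transcript, so these levels check the labels only in part.

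Chronic IFNy exposure of B16 before injection was compared with no exposure to ask which genes stay changed in the tumor. Antigen presentation and interferon genes were higher in the treated group (n = 3 against 3). The immunoproteasome subunit Psmb9 rose from 5.02 ± 4.01 to 48.2 ± 32.0 CPM (log2 fold change 3.20 ± 0.63, adjusted p = 0.0348), and Cd74, the chaperone of MHC class II, from 2.01 ± 2.09 to 43.3 ± 36.5 CPM (4.32 ± 0.92, adjusted p = 0.0378). The antiviral genes Oas2 (2.66 ± 0.51) and Ifit1 (2.51 ± 0.52) and the guanylate-binding protein gene Gbp3 (2.79 ± 0.56, a family with similar paralogs, so its share of reads is uncertain) also rose, each with adjusted p = 0.0348. B2m (1.38 ± 0.39, adjusted p = 0.0987), the PD-L1 gene Cd274 (1.5 ± 0.40, adjusted p = 0.0757) and Stat1 (1.35 ± 0.36, adjusted p = 0.0744) did not pass. Among the genes that fell were the lipid transporter gene Abca12 (-0.79 ± 0.19, adjusted p = 0.0459) and the nucleolar protein gene Ncl (-0.69 ± 0.16, adjusted p = 0.0368).

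Of 18 measured MHC class I presentation genes, 10 rose after IFNy over all genes tested and 18 adjusted over the list alone. Of 7 MHC class II genes, 3 rose (7 adjusted over the list alone), of 36 genes associated with type I interferon 18 rose (36 adjusted over the list alone), and of 21 associated with type II interferon 3 rose (21 adjusted over the list alone). All 4 lists passed the list test, also with an estimated correlation (adjusted p = 0.0366, 0.0451, 0.0366 and 0.0483 with an estimated correlation). In total 94 genes passed, 83 higher and 11 lower, with 60 higher and 4 lower by over 2-fold. The count rested on single libraries. It was 0 without untreated replicate 1 (971 genes at an unadjusted p under 0.05), 19 without untreated replicate 2, and 335 without untreated replicate 3. It was 433 without treated replicate 1, 0 without treated replicate 2 (1052 genes at an unadjusted p under 0.05) and 260 without treated replicate 3. These counts are by edgeR, where DESeq2 called 203 with every library. Untreated replicate 1 stands apart in its group, with a Spearman rho of -0.344 between its deviation from the mean library and transcript GC content (0.141 and 0.107 in replicates 2 and 3) and a chi-square per degree of freedom of 26.5 and 31.1 against them, where they had 7.35 against each other. Treated replicate 1 stands apart in its own group, with 15.8 against each of replicates 2 and 3, which had 4.75 against each other. Without untreated replicate 1 or 2 or treated replicate 2, 0 members of the 4 lists passed over all genes, while at least 17, 6, 32 and 20 members passed adjusted over the list alone. With the 2 groups fitted alone, 0 members passed over all genes, and adjusted over the list alone 0 MHC class I, 3 MHC class II, 0 type I and 0 type II members passed. Over all genes, 17 MHC class I and 13 type II members passed without untreated replicate 3, 6 MHC class I and 6 type I members without treated replicate 1, and 18, 6, 33 and 19 members without treated replicate 3. Treated replicate 3 came from cells exposed for 3 weeks and the others from cells exposed for 2, and its Stat1 level of 43.0 CPM lay within the untreated range of 23.6 to 48.1.

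**Figure D1:**
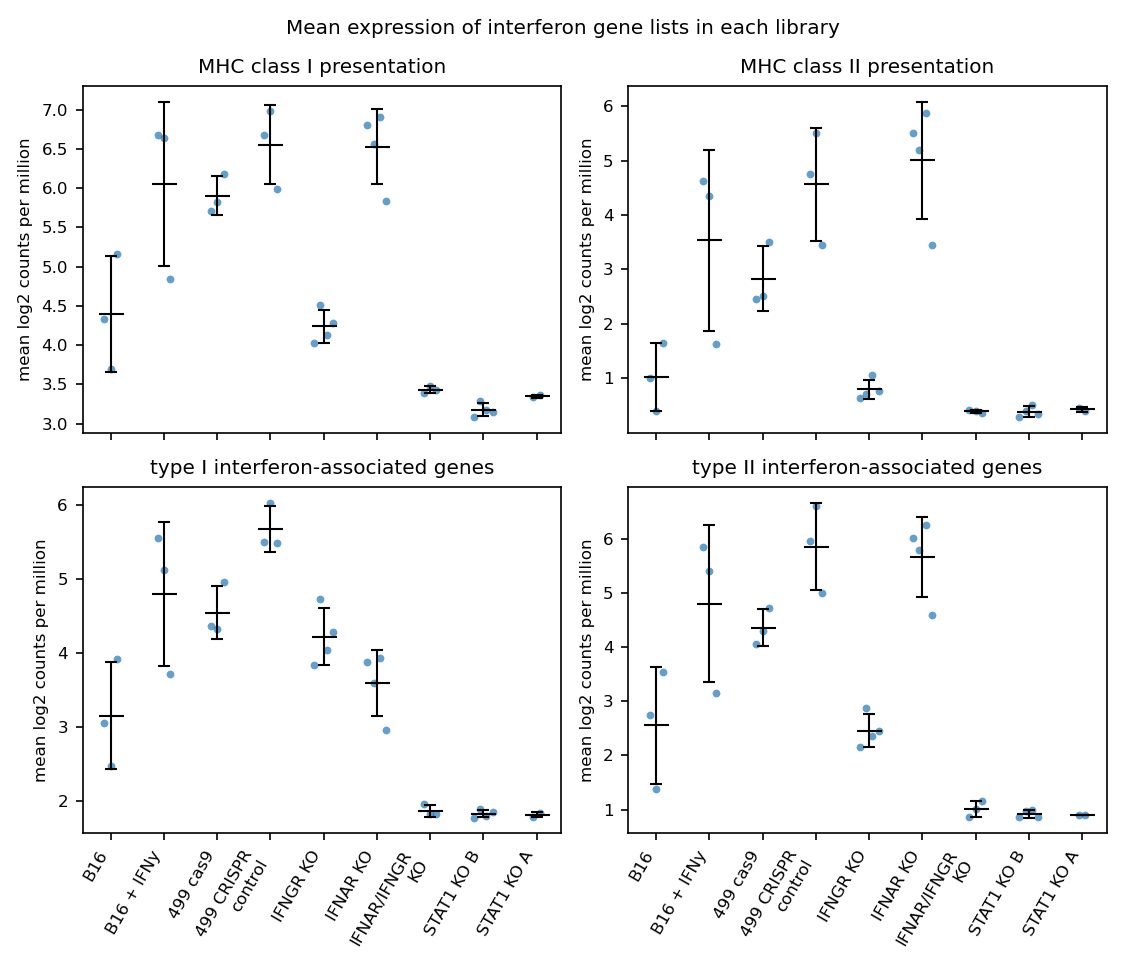
Mean log2 CPM of 4 interferon gene lists (vertical axes) in each of the 29 libraries (points), by group (horizontal axes), with the group mean and SD (bars). The MHC class I mean is 6.55 in the CRISPR control and 6.53 in the IFNAR knockout, against 4.24 in the IFNGR knockout and 3.17 in STAT1 knockout set B.

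The resistant line was compared with its parent through 499 with cas9 and untreated B16. The T cell inhibitory ligand gene Cd274 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), encoding PD-L1, rose from 7.56 ± 3.05 to 45.2 ± 9.77 CPM (log2 fold change 2.56 ± 0.38, n = 3 against 3, adjusted p = 8.29e-05). Lgals9, encoding galectin-9, rose from 15.7 ± 3.61 to 34.7 ± 5.17 CPM (1.13 ± 0.21, adjusted p = 0.000309). Interferon genes rose with them: Oas2 (2.62 ± 0.51), the interferon regulatory factor genes Irf7 (2.69 ± 0.65) and Irf9 (1.22 ± 0.25), the peptide transporter gene Tap2 (2.04 ± 0.49) and Psmb9 (2.68 ± 0.64), with adjusted p between 0.000983 for Oas2 and 0.00782 for Irf7. B2m (1.13 ± 0.39, adjusted p = 0.0533) and H2-K1 (1.01 ± 0.36, adjusted p = 0.062) missed the threshold. Pigment cell genes rose, among them Pmel (1.0 ± 0.12, adjusted p = 1.26e-06), a structural protein of melanosomes, and Trpm1 (0.97 ± 0.19, adjusted p = 0.000679). Top2a, a topoisomerase of dividing cells, fell from 646 ± 12.6 to 349 ± 50.3 CPM (-0.89 ± 0.13, adjusted p = 2.77e-05).

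Outside the lists, genes that separated the lines included Spp1, encoding osteopontin (4.57 ± 0.26, adjusted p = 3.03e-13), the potassium channel gene Kcnj13 (4.39 ± 0.38, adjusted p = 4.48e-08) and Irf4 (4.02 ± 0.38, adjusted p = 9.64e-09), a transcription factor active in pigment cells. Kalrn, a Rho guanine nucleotide exchange factor, reached 146 ± 31.9 CPM in 499 with cas9, and its count ratio to B16 was 2000 (95% counting interval 359 to 79100), from 1 count in the untreated libraries. Among the genes that fell were Galnt6 (-6.44 ± 0.47, adjusted p = 6.46e-10), a glycosyltransferase gene, Pcsk9 (-2.48 ± 0.28, adjusted p = 3.12e-07) and the ETS factor gene Etv5 (-1.97 ± 0.21, adjusted p = 2.59e-07). In the dedifferentiation and mesenchymal list, 5 of 10 genes rose and 1 fell (6 and 1 adjusted over the list alone, adjusted p = 0.175 with an estimated correlation), with Sox9 at 3.32 ± 0.53 and the cadherin gene Cdh2 at -0.71 ± 0.13. The 5 became 3 without untreated replicate 1 or cas9 replicate 3 and 2 without untreated replicate 2 or cas9 replicate 1. With the CRISPR control in place of cas9, 2 rose (2 adjusted over the list alone). Fibroblast markers moved with this list: 4 of 7 rose with cas9 and 0 with the CRISPR control.

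By list, 10 of 18 MHC class I genes rose in 499 with cas9 (16 adjusted over the list alone), 23 of 36 type I genes (26 adjusted over the list alone), 6 of 21 type II genes (7 adjusted over the list alone) and 9 of 17 pigmentation genes (9 adjusted over the list alone). Of 20 cell cycle genes 10 fell (12 adjusted over the list alone). These 5 lists passed the test with a preset correlation and missed it with an estimated one. The pigmentation list had adjusted p = 0.0524 with an estimated correlation and the other 4 adjusted p = 0.175 with an estimated correlation. Over all genes 2065 passed, 1029 higher and 1036 lower, with 304 higher and 193 lower by over 2-fold. The interferon counts moved with single libraries, among them untreated replicate 1, which stands apart in its group as described above. Without untreated replicate 1, untreated replicate 2 or cas9 replicate 3 in turn, MHC class I genes numbered 5, 5 and 5, type I genes 10, 8 and 10, and type II genes 0, 1 and 0. Without cas9 replicate 2 the type II genes numbered 3. Adjusted over the list alone, MHC class I genes numbered 5 without untreated replicate 2 and type I genes 15 without cas9 replicate 3, and type II genes 0 without untreated replicate 1, untreated replicate 2 or cas9 replicate 3 and 17 without untreated replicate 3. Cell cycle genes numbered 4 without untreated replicate 3, 6 without cas9 replicate 2 and 6 without cas9 replicate 3. With the CRISPR control in place of cas9, Top2a no longer passed (adjusted p = 0.223), 3 cell cycle genes fell, and 16 MHC class I, 35 type I and 21 type II genes were higher than in B16. With the replicate number as a block, 971 genes passed.

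STAT1 was removed from 499 to ask which genes depend on interferon signalling, and set B was compared with the CRISPR control. Antigen presentation genes fell. B2m, the shared light chain of MHC class I, fell from 1393 ± 344 to 93.0 ± 22.8 CPM (log2 fold change -3.91 ± 0.40, n = 4 against 3, adjusted p = 2.65e-07). The peptide transporter gene Tap1 fell from 143 ± 55.0 to 1.88 ± 0.611 CPM (-6.19 ± 0.75, adjusted p = 3e-06). The immunoproteasome gene Psmb8 was at 0 counts in all 4 knockouts, at least 497-fold lower against a floor of 3 counts over the group. The RNA sensor gene Ddx58 (-4.87 ± 0.42, adjusted p = 1.88e-08), Ifit2 (-1.90 ± 0.17, adjusted p = 1.17e-09) and Irf1 (-3.35 ± 0.49, adjusted p = 3e-05) fell, and Irf7 was at least 110-fold lower. Lgals9 fell from 86.8 ± 3.65 to 11.3 ± 2.41 CPM (-2.92 ± 0.21, adjusted p = 1.23e-11) and Cd274 from 49.3 ± 5.94 to 18.9 ± 7.57 CPM (-1.35 ± 0.34, adjusted p = 0.00549).

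Of the measured members in STAT1 knockout set B, 18 of 18 MHC class I, 7 of 7 MHC class II, 35 of 36 type I and 21 of 21 type II genes fell, with the same numbers adjusted over the list alone. These lists passed with an estimated correlation except MHC class II (adjusted p = 0.0516 with an estimated correlation), in which 4 genes fell against 499 cas9. Of 17 pigmentation genes 13 fell (14 adjusted over the list alone, adjusted p = 0.0157 with an estimated correlation), led by Trpm1 (-1.80 ± 0.17, adjusted p = 1.88e-08), Oca2 (-1.23 ± 0.14, adjusted p = 4.65e-08) and Tyr (-0.82 ± 0.10, adjusted p = 2.64e-07), while the receptor tyrosine kinase gene Kit of the same list rose (3.43 ± 0.37, adjusted p = 7.48e-08). The receptor kinase gene Axl fell (-4.28 ± 0.51, adjusted p = 1.66e-06). Of 17 hypoxia and glycolysis genes 9 rose and 1 fell (9 and 1 adjusted over the list alone, adjusted p = 0.289 with an estimated correlation), with the peptide hormone gene Adm at 3.50 ± 0.27 and Hk2, encoding a hexokinase, at 0.63 ± 0.11. Other genes that rose were Kalrn (5.38 ± 0.25, adjusted p = 2.1e-15), Gcnt1 (4.59 ± 0.40, adjusted p = 4.63e-10) and Tenm4 (3.85 ± 0.38, adjusted p = 1.91e-08). For single genes much of the rise lies in the low CRISPR control. The hypoxia and glycolysis count was 9 against 499 cas9 too, though these need not be the same genes. Against 499 cas9 the log2 fold change was 0.44 for Kalrn, 0.78 for Adm, 1.10 for Gcnt1, 1.39 for Kit and 2.06 for Tenm4.

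In total 3306 genes passed in STAT1 knockout set B, 1619 higher and 1687 lower, with 497 higher and 415 lower by over 2-fold. With 499 cas9 as the control, 1554 of them passed in the same direction, an alternative chosen after the data were examined. The count was 2108 without CRISPR control replicate 1. It was 2390 without set B replicate 21, which stands apart in its group, with a chi-square per degree of freedom of 7.57 to 9.81 against the others, which had 2.25 to 2.68 among themselves. Expression from chromosomes 12 and 13 differed between the CRISPR control and all other groups, and 318 of the 3306 calls were on these chromosomes. They hold 432 and 473 of the 12520 tested genes, so many calls would lie there without a shift.

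Set A of the STAT1 knockout was compared with 499 with cas9, which shares no library with the previous comparison. Stat1 fell (log2 fold change -3.36 ± 0.49, n = 2 against 3, adjusted p = 0.000195), and so did Tap1, from 73.3 ± 20.1 to 2.10 ± 0.474 CPM (-5.12 ± 0.87, adjusted p = 0.00109), Ddx58 (-4.51 ± 0.53, adjusted p = 1.51e-05), Oas1a (-3.90 ± 0.52, adjusted p = 4.47e-05, with reads possibly shared among the Oas1 paralogs) and Lgals9 (-2.49 ± 0.27, adjusted p = 4.35e-07). Cd274 was lower without passing (-1.24 ± 0.38, adjusted p = 0.0578). Top2a rose from 349 ± 50.3 to 605 ± 47.6 CPM (0.79 ± 0.15, adjusted p = 0.000961), as did Chsy1, a chondroitin synthase gene (1.56 ± 0.18, adjusted p = 7.38e-07), and Tenm4 (1.95 ± 0.29, adjusted p = 1e-04). Of 18 MHC class I genes 15 fell (18 adjusted over the list alone), of 36 type I genes 32 (35 adjusted over the list alone) and of 21 type II genes 16 (19 adjusted over the list alone), each list also passing with an estimated correlation. Of 20 cell cycle genes 8 rose (16 adjusted over the list alone, adjusted p = 0.0393 with an estimated correlation). The pigmentation falls of set B were fewer and weaker in set A: 0 of 17 genes fell and 1 rose (3 and 1 adjusted over the list alone, adjusted p = 0.68 with an estimated correlation). At an unadjusted p under 0.05, 6 were lower and 1 higher, and DESeq2 called 2 lower and 1 higher. The mean log2 CPM was 9.33 in set A and 9.38 in cas9. Leaving out cas9 replicates 1, 2 and 3 and set A replicates 1 and 3 in turn, 0, 2, 0, 1 and 0 fell (0, 5, 1, 2 and 0 adjusted over the list alone), and the 1 that rose was lost without set A replicate 1. Against the CRISPR control 9 fell in set A. In set B (mean log2 CPM 9.02) 10 fell against 499 cas9, so the counts of the sets also differed against the same control. Set A and cas9 belong to the deeper libraries and set B to the shallower ones, and set A has 2 libraries where set B has 4. These counts therefore cannot tell a difference between the sets from depth, batch or group size.

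The comparison of set A called 708 genes, 279 higher and 429 lower, with 69 higher and 228 lower by over 2-fold. With 2 knockout libraries it leaned on each: 181 genes passed without set A replicate 3, 467 without set A replicate 1, 435 without cas9 replicate 1 and 357 without cas9 replicate 3. Leaving out a knockout library assumes that the other varies like the remaining groups. Without set A replicate 3 the MHC class I, type I, type II and cell cycle counts were 2, 14, 0 and 4, and without replicate 1 MHC class I, type II and cell cycle numbered 9, 4 and 3, the last 7 adjusted over the list alone. Against the CRISPR control, 2935 genes passed and Top2a did not (adjusted p = 0.546), while 6 cell cycle genes rose. In set B 4 cell cycle genes rose against the CRISPR control (2 adjusted over the list alone) and 8 against 499 cas9. Of the genes called in set A, 154 were higher and 312 lower in set B as well, where 36.1 and 57.8 would be shared by chance, and 5 were called in opposite directions.

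IFNGR was knocked out to separate type II from type I signalling. MHC class I and class II genes were far below the CRISPR control. B2m fell from 1393 ± 344 to 310 ± 52.2 CPM (log2 fold change -2.17 ± 0.37, n = 4 against 3, adjusted p = 0.000379), Tap1 from 143 ± 55.0 to 14.7 ± 5.78 CPM (-3.26 ± 0.54, adjusted p = 0.000333) and Cd74 from 74.5 ± 47.1 to 0.719 ± 0.136 CPM (-6.61 ± 1.06, adjusted p = 0.00024). The transcription factor gene Irf1 (-2.59 ± 0.45, adjusted p = 0.000515) and the interferon-inducible GTPase gene Igtp (-4.81 ± 0.74, adjusted p = 0.000167) fell, and Ciita, the master regulator of MHC class II, was at 0 counts, at least 32.9-fold lower. Its call was lost without CRISPR control replicate 2 (adjusted p = 0.0759). Cd274 fell from 49.3 ± 5.94 to 18.2 ± 3.34 CPM (-1.43 ± 0.34, adjusted p = 0.00642). Type I genes fell as well, for example Ifit2 (-1.25 ± 0.16, adjusted p = 3.33e-06) and Dtx3l (-1.21 ± 0.22, adjusted p = 0.000515). Pmel (-0.81 ± 0.12, adjusted p = 1.16e-05) and Mitf (-0.68 ± 0.12, adjusted p = 0.000321), the lineage transcription factor gene of melanocytes, fell.

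In the IFNGR knockout, 18 of 18 MHC class I, 7 of 7 MHC class II and 20 of 21 type II genes fell (18, 7 and 21 adjusted over the list alone), all with an estimated correlation too. Of 36 type I genes 28 fell (33 adjusted over the list alone, adjusted p = 0.0787 with an estimated correlation), and of 8 T cell inhibitory ligands 5 (5 adjusted over the list alone, adjusted p = 0.0166 with an estimated correlation). Of 17 pigmentation genes 11 fell and 1 rose (11 and 1 adjusted over the list alone, adjusted p = 0.0166 with an estimated correlation). In total 1585 genes passed, 703 higher and 882 lower, with 263 higher and 238 lower by over 2-fold. Tenm4 (3.52 ± 0.38, adjusted p = 5.91e-07) and the metalloprotease gene Adam12 (2.72 ± 0.28, adjusted p = 8.49e-07) were among those that rose, by 1.73 and 1.11 against 499 cas9. Against 499 cas9, 6 pigmentation genes fell (8 adjusted over the list alone) and 3 inhibitory ligands. The control decided the type I result. Against 499 cas9, 0 of 36 type I genes fell by edgeR, Ifit2 (adjusted p = 0.955) and Dtx3l (adjusted p = 0.304) no longer passed, and 487 genes passed against both controls. Against cas9, 16 MHC class I, 3 MHC class II and 10 type II genes still fell. Without CRISPR control replicate 1 the total was 1004. Without CRISPR control replicate 2 the type I genes numbered 15 and the inhibitory ligands 2, and without IFNGR knockout replicate 1 the type I genes numbered 18. Of the 1585 calls, 202 were on chromosomes 12 and 13, which hold 432 and 473 of the 12520 tested genes.

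IFNAR was knocked out for the converse question. Type I genes fell and antigen presentation did not pass the test. Ddx58 fell from 139 ± 9.74 to 20 ± 5.76 CPM (log2 fold change -2.80 ± 0.35, n = 4 against 3, adjusted p = 1.98e-05), Oas2 from 15.3 ± 4.03 to 0.542 ± 0.386 CPM (-4.79 ± 0.67, adjusted p = 4.8e-05). Usp18, a negative regulator of the type I receptor (-4.24 ± 0.70, adjusted p = 0.000591), and Trim30a (-3.90 ± 0.49, adjusted p = 2.47e-05) fell as well. Lgals9 fell from 86.8 ± 3.65 to 18.9 ± 4.90 CPM (-2.22 ± 0.20, adjusted p = 6.22e-09). B2m (-0.38 ± 0.36, adjusted p = 0.612), Cd74 (0.62 ± 0.59, adjusted p = 0.619), Irf1 (0.29 ± 0.40, adjusted p = 0.752) and Cd274 (-0.16 ± 0.33, adjusted p = 0.84) did not pass, and without IFNAR knockout replicate 4 the Cd274 value was 0.045. Slit2, a guidance factor gene (2.71 ± 0.22, adjusted p = 5.75e-10), rose.

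In the IFNAR knockout, 31 of 36 type I genes fell (35 adjusted over the list alone, adjusted p = 0.0179 with an estimated correlation). By edgeR, 0 of 18 MHC class I and 0 of 7 MHC class II genes passed in either direction, also adjusted over the list alone, at an unadjusted p under 0.05 and by DESeq2. Of 21 type II genes 1 fell (0 adjusted over the list alone), Cxcl10, at -1.09 ± 0.33 (adjusted p = 0.0433); its call was lost without CRISPR control replicate 1 (adjusted p = 0.11) or 2 (0.21) or IFNAR knockout replicate 1 (0.0884), 3 (0.0735) or 4 (0.129). Of 17 pigmentation genes 9 fell and 1 rose (10 and 1 adjusted over the list alone, adjusted p = 0.071 with an estimated correlation), 5 fell without CRISPR control replicate 1 and 0 fell against 499 cas9. In total 927 genes passed, 450 higher and 477 lower, with 157 higher and 113 lower by over 2-fold. Without CRISPR control replicate 1 the total was 482, and 223 genes passed against both controls. Against 499 cas9, 9 type I genes fell, among them Ddx58, Oas2, Usp18 and Trim30a. Of the 927 calls, 155 were on chromosomes 12 and 13, which hold 432 and 473 of the 12520 tested genes.

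**Figure D2:**
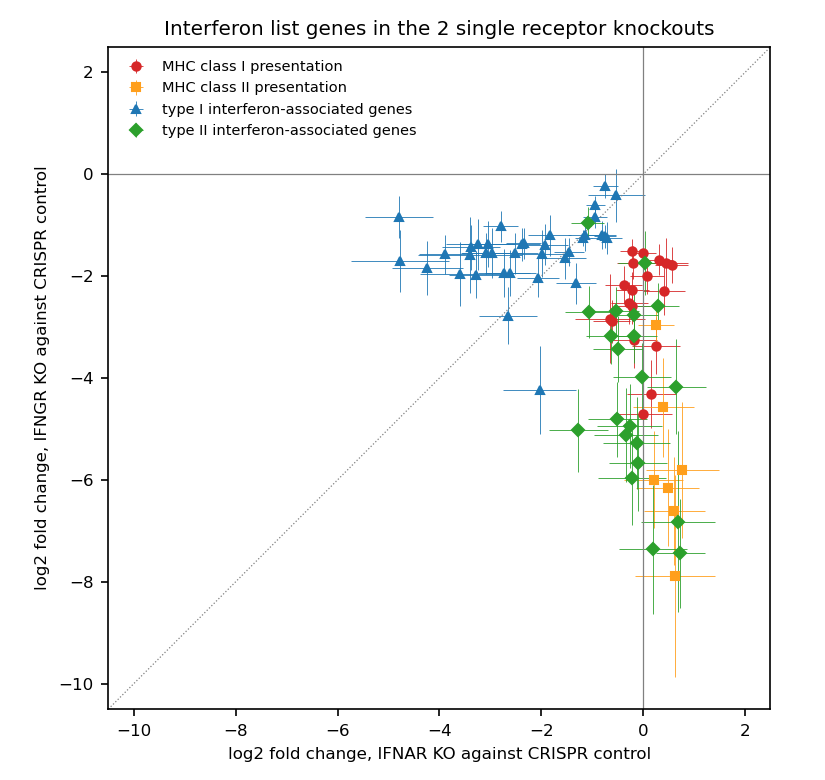
Log2 fold changes ± SE of the members of 4 interferon gene lists in the IFNAR knockout (horizontal axis) and the IFNGR knockout (vertical axis), each against the same 3 CRISPR control libraries, with the dotted line marking equal values. Psmb9 and Cd74 lie at -4.31 and -6.61 on the vertical axis, and Oas2 at -4.79 on the horizontal axis.

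The double receptor knockout was compared with the CRISPR control to remove both signals. B2m fell from 1393 ± 344 to 111 ± 16 CPM (log2 fold change -3.65 ± 0.44, n = 3 against 3, adjusted p = 5.69e-06), Tap1 from 143 ± 55.0 to 3.8 ± 1.02 CPM (-5.22 ± 0.74, adjusted p = 4.23e-05), Ddx58 from 139 ± 9.74 to 5.28 ± 2.14 CPM (-4.68 ± 0.45, adjusted p = 3e-07) and Stat1 from 164 ± 55.0 to 16.3 ± 2.86 CPM (-3.32 ± 0.41, adjusted p = 7.66e-06). Lgals9 (-2.56 ± 0.22, adjusted p = 4.99e-09) and Cd274 (-2.20 ± 0.40, adjusted p = 0.000431) both fell. The interferon-stimulated gene Isg15 was lower by a count ratio of 84.9 (95% counting interval 28.6 to 415). Kit (3.21 ± 0.39, adjusted p = 1.21e-06), Adam12 (2.73 ± 0.29, adjusted p = 7.6e-07) and Tenm4 (2.95 ± 0.41, adjusted p = 1.19e-05) rose, by 1.17, 1.13 and 1.15 against 499 cas9.

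All 18 MHC class I, 7 MHC class II and 21 type II genes measured and 35 of 36 type I genes fell in the double knockout, with the same numbers adjusted over the list alone, and the 4 lists passed with an estimated correlation. Of 17 pigmentation genes 10 fell and 1 rose (10 and 1 adjusted over the list alone, adjusted p = 0.126 with an estimated correlation), and 1 fell against 499 cas9. The mean log2 CPM of the pigmentation list was 9.30, against 9.49 in the CRISPR control, 9.38 in 499 cas9 and 9.17 in the IFNGR knockout. In total 2247 genes passed, 920 higher and 1327 lower, with 347 higher and 342 lower by over 2-fold. The count was 1495 without CRISPR control replicate 1 and 1436 without CRISPR control replicate 2. Against 499 cas9, 550 genes passed, with 16 MHC class I, 1 MHC class II, 30 type I and 13 type II genes among those that fell, and 354 passed against both controls. Of the 2247 calls against the CRISPR control, 284 were on chromosomes 12 and 13, which hold 432 and 473 of the 12520 tested genes.

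The knockouts were then compared with each other, without any control library. Between the single knockouts, the IFNGR knockout had lower antigen presentation and type II genes than the IFNAR knockout: Psmb9 (log2 fold change -4.47 ± 0.64, n = 4 against 4, adjusted p = 0.000646), Cd74 (-7.22 ± 0.99, adjusted p = 0.000434) and Irf1 (-2.88 ± 0.43, adjusted p = 0.000685). It had higher Oas2 (3.96 ± 0.69, adjusted p = 0.00165), Ddx58 (1.78 ± 0.34, adjusted p = 0.00404), Lgals9 (0.99 ± 0.20, adjusted p = 0.00316) and Tenm4 (2.27 ± 0.29, adjusted p = 0.000105). Of the lists, 17 of 18 MHC class I, 7 of 7 MHC class II and 18 of 21 type II genes were lower in the IFNGR knockout (18, 7 and 20 adjusted over the list alone), all also with an estimated correlation, and 3 of 36 type I genes were higher (11 adjusted over the list alone, adjusted p = 0.417 with an estimated correlation). The 11 became 3 without IFNAR knockout replicate 1, 2 or 4 or IFNGR knockout replicate 2 or 4, 7 without IFNAR knockout replicate 3 and 6 without IFNGR knockout replicate 3. In total 282 genes differed, 97 higher and 185 lower, and 171 without IFNAR knockout replicate 2.

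The double knockout had lower type I genes than the IFNGR knockout. Ddx58 (log2 fold change -3.66 ± 0.45, n = 3 against 4, adjusted p = 0.000123), Trim25 (-1.72 ± 0.27, adjusted p = 0.000484), Irf9 (-2.11 ± 0.30, adjusted p = 0.000199) and Lgals9 (-1.33 ± 0.22, adjusted p = 0.000429) were lower. Of 36 type I genes 28 were lower (34 adjusted over the list alone, adjusted p = 0.0112 with an estimated correlation). Of 21 type II genes 1 was lower (5 adjusted over the list alone, adjusted p = 0.341 with an estimated correlation), 0 without double knockout replicate 3, 5 or 6 or IFNGR knockout replicate 2, where 0, 2, 0 and 1 passed adjusted over the list alone. DESeq2 called 12 lower, and the mean log2 CPM of the list was 2.46 in the IFNGR and 1.01 in the double knockout. Of 18 MHC class I genes 1 was lower (1 adjusted over the list alone, adjusted p = 0.515 with an estimated correlation), 0 without any 1 of the 7 libraries, and DESeq2 called 4 lower. The mean log2 CPM of the MHC class I list was 4.24 (4.03 to 4.51) in the IFNGR knockout. In the double knockout it was 3.43 (3.38 to 3.48), and the list passed camera with the preset correlation (adjusted p = 1.54e-05). The few calls therefore do not show an equal level. By edgeR 0 of 7 MHC class II genes passed, also adjusted over the list alone, at an unadjusted p under 0.05 and by DESeq2. In total 499 genes differed, 79 higher and 420 lower, and among the higher were Vwf (1.13 ± 0.23, adjusted p = 0.00434) and the nuclear RNA Neat1 (0.93 ± 0.14, adjusted p = 0.000199). The log2 fold changes followed transcript GC content, and 193 genes differed after each library's GC trend was removed, an alternative chosen after the data were examined. The total was 263 without double knockout replicate 3 and 185 without double knockout replicate 5, where 16 type I genes were lower.

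Against the IFNAR knockout, the double knockout had lower B2m (log2 fold change -3.27 ± 0.42, n = 3 against 4, adjusted p = 0.000101), Tap2 (-5.09 ± 0.65, adjusted p = 9.78e-05), Irf8 (-6.15 ± 0.85, adjusted p = 0.00013), a transcription factor gene induced by IFNy, and Cd274 (-2.03 ± 0.39, adjusted p = 0.00164). The type I genes Parp14 (-3.52 ± 0.59, adjusted p = 0.000743) and Dtx3l (-1.59 ± 0.26, adjusted p = 0.000328) were lower as well. Of the lists, 17 of 18 MHC class I, 7 of 7 MHC class II, 20 of 21 type II and 21 of 36 type I genes were lower (18, 7, 21 and 28 adjusted over the list alone), all also with an estimated correlation. In total 1148 genes differed, 302 higher and 846 lower. The total was 610 without double knockout replicate 3 and 727 without IFNAR knockout replicate 2, and 13 type I genes were lower without double knockout replicate 3 or 5.

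The genes that set 499 with cas9 apart from B16 were followed into the knockouts, which share no library with that comparison. The list was derived here from these libraries and was not fixed in advance. Of 1029 genes higher in 499, 430 fell and 101 rose in STAT1 knockout set B, 354 fell and 47 rose in the IFNGR knockout, 192 fell and 53 rose in the IFNAR knockout, and 350 fell and 51 rose in the double knockout, against the CRISPR control. Chance alone would give 139, 72.5, 39.2 and 109 falls. Of 1036 genes lower in 499, 285, 222, 110 and 174 rose and 29, 7, 9 and 72 fell. All 8 list tests passed with the preset correlation and 7 with an estimated one, the exception being the 499-lower genes in the double knockout (adjusted p = 0.272 with an estimated correlation). With the members of the interferon and presentation lists removed, 982 genes higher in 499 remained, of which 384, 312, 167 and 304 fell. The 499-higher genes were chosen against B16 and tested against the CRISPR control, which differed from cas9 as described next.

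The 2 controls of 499 carry no named knockout, and the CRISPR control was compared with cas9 to see how alike they were. All cas9 libraries belong to the deeper set and all CRISPR control libraries to the shallower one. A difference between these controls therefore cannot be told apart from depth or batch by this comparison alone. The same limit holds for knockouts of the shallower set measured against cas9. Kalrn fell from 146 ± 31.9 to 4.62 ± 1.44 CPM (log2 fold change -4.93 ± 0.25, n = 3 against 3, adjusted p = 8e-14), Jph2, a junctional membrane protein gene, from 19.3 ± 2.83 to 1.73 ± 1.84 CPM (-3.33 ± 0.39, adjusted p = 2.29e-06), and Adm from 58.8 ± 19.7 to 9.05 ± 2.12 CPM (-2.72 ± 0.29, adjusted p = 8.57e-07). Pdgfrb, a growth factor receptor gene, also fell (-3.43 ± 0.45, adjusted p = 8.89e-06). Igf2bp3, an RNA-binding protein gene (3.02 ± 0.33, adjusted p = 3.72e-07), Lgals9 (1.32 ± 0.19, adjusted p = 3.53e-05), Ifit2 (1.23 ± 0.17, adjusted p = 2.11e-05) and the antiviral kinase gene Eif2ak2 (0.83 ± 0.19, adjusted p = 0.00463) rose. Of 36 type I genes 17 were higher in the CRISPR control (27 adjusted over the list alone, adjusted p = 0.305 with an estimated correlation). So were 5 of 21 type II genes (21 adjusted over the list alone), 3 of 7 MHC class II genes (7 adjusted over the list alone) and 3 of 17 receptor and JAK-STAT genes (5 adjusted over the list alone), each with adjusted p = 0.321 with an estimated correlation. The mean log2 CPM of the type II list was 4.36 in cas9 and 5.86 in the CRISPR control, that of the type I list 4.55 and 5.68. Further, 5 of 17 pigmentation genes were higher and 1 lower (6 and 1 adjusted over the list alone, adjusted p = 0.321 with an estimated correlation).

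In total 1364 genes differed between the controls, 809 higher and 555 lower in the CRISPR control, with 118 higher and 229 lower by over 2-fold. The total was 897 without cas9 replicate 1, 884 without cas9 replicate 3, 732 without CRISPR control replicate 1 and 549 without CRISPR control replicate 2. CRISPR control replicate 4 stands apart in its group, with a chi-square per degree of freedom of 6.95 and 7.32 against replicates 1 and 2, which had 2.02 against each other. Without it the total was 1903, and the totals of STAT1 knockout set B and the IFNGR, IFNAR and double knockouts against this control were 3767, 1852, 1239 and 2686. The type I count was 3, 4, 5 and 2 without cas9 replicate 1, cas9 replicate 2, CRISPR control replicate 1 and CRISPR control replicate 2, and the pigmentation count 3 without cas9 replicate 1 and 2 without CRISPR control replicate 1. Without cas9 replicates 1, 2 and 3 and CRISPR control replicates 1, 2 and 4 in turn, the type II count was 0, 0, 1, 0, 0 and 15, the MHC class II count 0, 0, 1, 1, 0 and 5, and the JAK-STAT count 0, 0, 1, 1, 0 and 1. Adjusted over the list alone, the type II count in the same order was 0, 7, 20, 18, 0 and 21, the MHC class II count 1, 3, 7, 7, 0 and 7 and the JAK-STAT count 0, 0, 6, 1, 0 and 1, and the type I count was 2 without CRISPR control replicate 2. Genes of chromosome 13 were shifted up in the CRISPR control against cas9 by a median log2 fold change of 0.32 (473 genes tested, 116 called higher and 4 lower), and genes of chromosome 12 down by a median of -0.23 (432 genes tested, 5 called higher and 60 lower). Per library, the chromosome 13 median against untreated B16 was 0.28 to 0.37 in the CRISPR control and -0.05 to 0.12 in the 26 other libraries.

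**Figure D3:**
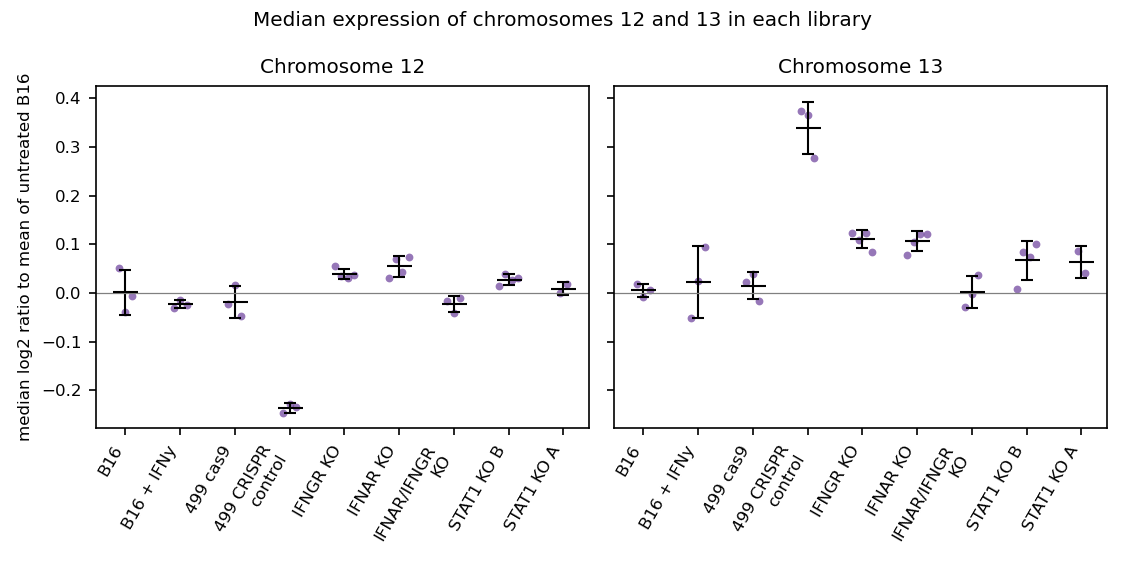
Median log2 ratio of the tested genes of chromosomes 12 and 13 to the mean of untreated B16 (vertical axis) in each library (points), by group (horizontal axes), with group mean and SD (bars). The 3 CRISPR control libraries lie at -0.25 to -0.23 on chromosome 12 and at 0.28 to 0.37 on chromosome 13.

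Overlaps were measured between comparisons that share control libraries. Chronic IFNy and 499 with cas9, both against the same 3 untreated B16 libraries, shared 52 genes higher and 8 lower, where 6.82 and 0.910 would be shared by chance, and 3 genes went in opposite directions. Without untreated replicate 1 or treated replicate 2, IFNy called 0 genes, so 0 can be shared. The covariance of their log2 fold changes across genes was 0.0960, against 0.0369 in simulated unchanged groups with the same controls, in which 0 genes were called in both. Their correlation was 0.384, below the 0.508 of the simulated unchanged groups. The IFNGR and IFNAR knockouts shared 309 genes higher and 337 lower than the CRISPR control, where 25.3 and 33.6 would be shared by chance, with a covariance of 0.228 against 0.0555 simulated and a correlation of 0.686 against 0.593. STAT1 knockout set B shared 645 higher and 875 lower genes with the double knockout, where 119 and 179 would be shared by chance, with a covariance of 0.728 against 0.0561 simulated and a correlation of 0.856 against 0.571. The 3 control libraries cannot be split into 2 sets of at least 2, so part of each excess can come from the shared controls. Of 486 genes called in the same direction in all 4 knockouts against the CRISPR control, 305 differed between the 2 controls in the opposite direction, and 26 were also called in that direction in all 4 against cas9. Of these 26, 0 were in the interferon and presentation lists.

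Markers of other cell types were low. Of the T and NK cell, B cell and muscle and adipocyte markers, 0 had enough counts to be tested, and of the myeloid, keratinocyte, endothelial, erythroid, pericyte and fibroblast markers 1, 1, 2, 2, 3 and 7 were tested. Summed fibroblast markers measured a median of 92.1 CPM over libraries (72.5 to 144). In 499 with cas9, 4 of 7 fibroblast markers rose against B16 (5 adjusted over the list alone, adjusted p = 0.175 with an estimated correlation), with the collagen gene Col1a2 at 2.39 ± 0.61 (adjusted p = 0.00762). The count was 1 without untreated replicate 1, untreated replicate 3 or cas9 replicate 1 and 2 without untreated replicate 2 or cas9 replicate 3, and it was 0 with the CRISPR control in place of cas9. The CRISPR control was low in the 3 pericyte markers (mean log2 CPM 1.01, against 2.27 in 499 cas9 and 2.52 in the double knockout). Against it 3 of 3 were higher in the double knockout (3 adjusted over the list alone, adjusted p = 0.014 with an estimated correlation) and 2 in STAT1 knockout set B and in the IFNGR knockout, while against 499 cas9 1 was higher in the double knockout, 1 in set B and 0 in the IFNGR knockout. With the 2 groups fitted alone 1 was higher in the double knockout. Between the controls, 4 of 7 fibroblast markers were lower in the CRISPR control (4 adjusted over the list alone, adjusted p = 0.26 with an estimated correlation) and 1 of 3 pericyte markers (2 adjusted over the list alone, adjusted p = 0.0433 with an estimated correlation). The 4 became 1 without cas9 replicate 1, 0 without cas9 replicate 3 or CRISPR control replicate 1 and 2 without CRISPR control replicate 2 or 4. The mean of the 2 endothelial markers was 2.62 in the CRISPR control and 3.79 in cas9. Between the single knockouts, 1 of the 2 endothelial markers and the 1 keratinocyte marker were lower in the IFNGR knockout. The first call was lost without IFNAR knockout replicate 1, 3 or 4 or IFNGR knockout replicate 2, 3 or 4, and the second without IFNAR knockout replicate 1 or 2 or IFNGR knockout replicate 1, 2 or 3. Summed erythroid markers measured 420 CPM in cas9 replicate 2, 17.2 in cas9 replicate 1 and a median of 4.57 over all libraries.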

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

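The tests of the CRISPR control, of GC content on all calls, of library size and of the longer treatment were chosen after the results were seen.

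The receptor knockouts differed from each other, tested directly. The numbers were 282 genes between the IFNGR and IFNAR knockouts, 499 between the double and IFNGR knockouts and 1148 between the double and IFNAR knockouts. The STAT1 knockout effect differed between set B against the CRISPR control and set A against 499 cas9 in 669 genes, 423 higher and 246 lower in set B, of which 1 was in the interferon and presentation lists, while 8 genes of the pigmentation list were lower and 1 higher. The MHC class I, MHC class II, type I and type II lists still differed at the median, by log2 values of -0.841, -2.18, -1.12 and -1.58. The CRISPR control lay above cas9 in the same lists, by medians of 0.865, 2.24, 1.105 and 1.66. The lack of calls therefore does not show an equal effect in both sets. In groups of 4 libraries, 0 of 30 pairs of group and measure held a library set apart from the others by more than the critical gap of Dixon's test, where chance gives about 1 in 20. The measures tested do not include the spread between replicates, in which set B replicate 21 stands apart (chi-square per degree of freedom of 7.57 to 9.81 against the others, 2.25 to 2.68 among them).

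Other splits of the same libraries into groups of the same sizes were fitted. For groups of 4 against 3 or 4 against 4, 1 split of 35, the real one, gave as many genes: 3306 for STAT1 knockout set B (highest other 1908), 1585 for the IFNGR knockout (337), 927 for the IFNAR knockout (237), 282 between the single knockouts (1), 499 between the double and IFNGR knockouts (1) and 1148 between the double and IFNAR knockouts (440). This is the smallest share that 35 splits can give. The comparisons reuse libraries and were not adjusted for their number, so chance is made less likely but is not excluded. For 3 against 3 the 10 splits are too few to reach so low a share: 2065 for 499 cas9 against B16 (highest other 0), 2247 for the double knockout (0), 1364 between the controls (521) and 94 for IFNy-treated B16 (822). For IFNy, 3 of the 10 splits gave as many genes, and the split with untreated replicates 1 and 2 and treated replicate 1 set against the rest gave 822, which points to a structure of the samples other than treatment.

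Outside the interferon and presentation lists, 458 genes were called in the same direction in all 4 knockouts against the CRISPR control, 207 higher and 251 lower. All libraries of these comparisons belong to the shallower set, so a batch difference between the deeper and the shallower libraries would cancel within them. Such a difference would shift STAT1 knockout set B against set A as it shifts the CRISPR control against cas9. The median ratio of these shifts was -0.0924 (quartiles -0.552 to 0.172). The genes were chosen for a CRISPR control that lies apart within the shallower set, which can lower this ratio. It therefore does not decide on batch, which stays open for comparisons of cas9 with the shallower libraries. Measured against cas9, the knockouts moved by a median of 0.311 of their shift from the CRISPR control (quartiles 0.115 to 0.528), so a CRISPR control line that differs from the other 499 lines may account for most of the shift; the genes were chosen against that control, which lowers the ratio in part. Loss of interferon signalling stays open as a partial explanation, since STAT1 knockout set A moved from cas9 by a median of 0.313 of the shift of set B (quartiles 0.101 to 0.521), and whether it acts on these genes cannot be told apart from the difference in controls. Of the 458 genes, 35 higher and 2 lower lay on chromosome 12 and 2 higher and 42 lower on chromosome 13.

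Between the double and the IFNGR knockout, genes higher in the double knockout had a median transcript GC content of 52.8% and genes lower 40.9%, against 49.2% for all genes tested (Spearman rho 0.326 across genes, which are not independent replicates). A difference in library size is argued against by the ratio of mean library sizes, 0.976. With each library's GC trend removed 193 genes passed in place of 499, so a GC bias of the libraries may account for many of the calls. For the type I list GC bias is argued against, because 26 of its 28 falls passed the threshold with the trend removed. The correlation with GC content was as large between the controls (rho -0.338), in IFNy-treated B16 (0.34) and between the double and IFNAR knockouts (0.314), where 996, 81 and 801 genes passed with the trend removed in place of 1364, 94 and 1148. No biological explanation of the GC trend was tested.

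The B16 library treated with IFNy for 3 weeks lay below the 2 libraries treated for 2 weeks in interferon genes. Of 260 genes called without it, it lay beyond all 3 untreated libraries on the treated side in 44.2% (38.5% of 218 higher genes and 73.8% of 42 lower genes). An untreated library under a wrong label cannot be told apart from a weakly responding treated one by this share, because interferon genes vary together and 3 untreated libraries do not show how far. A longer treatment also stays open, as 1 library was treated for 3 weeks. Leaving it out raised the count from 94 to 260.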

How the results depend on the processing

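The GC trend, the count against both controls and the list counts without single libraries were chosen after the results were seen. Of 386 called gene and comparison pairs named, 4499 of 4969 values under the alternatives kept direction and side of the threshold, 456 fell short of it and 14 reversed. Named genes were picked with preference for calls that do not rest on 1 library, and 2506 of the 4969 values come from leaving out 1 library. That choice can raise the share kept, which therefore does not measure how stable calls are in general. Of 24 named pairs not past the threshold, 252 of 309 values stayed so, 54 passed it and 3 reversed. RLE size factors kept every total within 1.5 times. The cause was not tested for the changes below unless stated. Without the filter on low counts, totals were 548 for IFNy, 1153 for STAT1 set A and 474 for IFNGR against IFNAR knockouts. The overlap of IFNy and 499 was then 219. DESeq2 gave 203 for IFNy and an overlap of 112. Fitting the 2 groups alone, which uses fewer samples, gave 0 for IFNy (1050 genes at an unadjusted p under 0.05) and an overlap of 0. In the same fits set B gave 2109, set A 383, the single knockouts 476, and the totals were 1301 and 1861 for the double against the IFNGR and IFNAR knockouts and 593 between the controls. The STAT1 sets then shared 283 genes. With the replicate number as a block, totals were 971 for 499 against B16, 1094 for set A and 452 between the single knockouts. The block kept the totals within 1.5 times at 69 for IFNy, 1600 for the IFNGR knockout, 792 for the IFNAR knockout and 1753 between the controls. Libraries met the rule for pairs of the same number in 0 of 7 comparisons, although in the IFNGR and IFNAR knockouts 3 of 3 correlated best with the control of their number (lowest r 0.0524 and 0.0458).

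Against 499 cas9 the double knockout gave 550, and against the CRISPR control set A gave 2935. Genes called against both controls numbered 1554 for set B, 487 for the IFNGR, 223 for the IFNAR and 354 for the double knockout. With the GC trend removed the double and IFNGR knockouts differed in 193 genes. List tests passed 45 times with an estimated correlation in place of 94. Leaving out each library in turn gave 0 to 433 genes for IFNy, 1401 to 1952 for 499, 2108 to 3767 for set B, 1004 to 1852 for the IFNGR, 482 to 1239 for the IFNAR and 1436 to 2686 for the double knockout. It gave 181 to 854 for set A, 171 to 287 between the single knockouts, 185 to 377 and 610 to 1092 for the double against the IFNGR and IFNAR knockouts, and 549 to 1903 between the controls.

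Signs turned with the control. With the CRISPR control in place of cas9 against B16, log2 fold changes were -0.45 for Fosb, -0.48 for Egr1, -0.76 for Col1a1 and -0.38 for Col1a2. Against cas9, the IFNGR knockout gave 0.25 for Isg15, 0.20 for Ifit1, 0.09 for Lgals9, -0.86 for Kalrn, -0.25 for Lamb1 and -0.35 for Adm. The IFNAR knockout gave 0.65 for Stat1, 0.051 for Ifit2, 0.60 for B2m, 0.004 for Cxcl10 and -0.67 for Kalrn, and the double knockout -1.63 for Kalrn. Cd274 in the IFNAR knockout, against the CRISPR control, ranged from -0.243 without IFNAR knockout replicate 3 to 0.045 without IFNAR knockout replicate 4. At 1871800 to 6564400 counts per library, ratios for genes at 0 to 3 counts are bounded rather than measured, and at most 76 of 100 genes changed by 2-fold were recovered in simulated data.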

Other observations

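The tests of chromosomes 12 and 13 were chosen after the result was seen.

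Some signalling genes fell in the knockouts. Of 17 interferon receptor and JAK-STAT genes, the targeted Stat1 among them, 8 fell and 1 rose in STAT1 knockout set B (9 and 1 adjusted over the list alone, adjusted p = 0.0157 with an estimated correlation). In the double knockout 8 fell (8 adjusted over the list alone, adjusted p = 0.0057 with an estimated correlation). Against 499 cas9, 5 fell in set B and 4 in the double knockout. Irf9, a partner of STAT1 and STAT2 in the type I response, had log2 fold changes of -3.36 ± 0.29 (adjusted p = 2.74e-09) and -3.01 ± 0.30 (adjusted p = 1.41e-07) in these knockouts, and -1.42 ± 0.25 in the IFNAR knockout (adjusted p = 0.000432). Of 8 T cell inhibitory ligands, 4 fell in set B (4 adjusted over the list alone, adjusted p = 0.019 with an estimated correlation), among them Nectin2 at -0.73 ± 0.16 (adjusted p = 0.000896).

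Some hypoxia and glycolysis genes were higher in the receptor knockouts than in the CRISPR control, without the list passing with an estimated correlation. Of 17 genes, 4 rose in the IFNGR knockout (4 adjusted over the list alone, adjusted p = 0.455 with an estimated correlation) and 5 in the IFNAR knockout (8 adjusted over the list alone, adjusted p = 0.177 with an estimated correlation). There were 5 in the double knockout (5 adjusted over the list alone, adjusted p = 0.369 with an estimated correlation), which became 3 without double knockout replicate 5 or CRISPR control replicate 1 or 4. Against 499 cas9, 3, 4 and 2 genes rose. Adm, higher in all 3 against the CRISPR control, did not pass against cas9 (adjusted p = 0.282, 0.78 and 0.353). Of 13 immediate early and heat shock genes, 7 rose in 499 cas9 against B16 (9 adjusted over the list alone, adjusted p = 0.0803 with an estimated correlation), with Jun at 0.92 ± 0.20 (adjusted p = 0.00263). The count was 3 without untreated replicate 1 or cas9 replicate 1 and 4 without untreated replicate 2 or 3, and 1 with the CRISPR control in place of cas9. Of 7 NF-kB and inflammatory cytokine genes, 3 fell in the double knockout (3 adjusted over the list alone), Ccl5, Csf1 and Birc3. The list missed the threshold with either correlation (adjusted p = 0.328 with an estimated correlation). Without double knockout replicate 3 or 5 or CRISPR control replicate 4, or with 499 cas9 as the control, 1 fell.

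A hypothesis is that the CRISPR control line carries whole-chromosome copy number differences, with a gain of chromosome 13 and a loss of chromosome 12. Of 24 windows of 10 Mb with at least 10 genes on these chromosomes, 100% had a median on the side of their chromosome, 12 of 12 higher on chromosome 13 and 12 of 12 lower on chromosome 12, as a change of the whole chromosome may give. This counts signs only. The window medians ranged from 0.191 to 0.539 on chromosome 13 and from -0.321 to -0.019 on chromosome 12, so some windows of chromosome 12 were hardly shifted. Both chromosomes were picked for their medians in these data, and chromosomes 5 and 6 had medians of -0.146 each between the controls. GC bias is argued against, because the chromosome 13 median of 0.318 was 0.283 with each library's GC trend removed. A change in the 499 cas9 line is argued against as well: the 4 knockouts lay at a mean chromosome 13 median of 0.0333 from cas9 (-0.0421 to 0.0866). DNA was not measured, so copy number itself was not tested.

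Between 499 cas9 and untreated B16, the largest absolute chromosome median was 0.101 (log2, chromosome X, lower in 499). The SD of the 20 chromosome medians was 0.0532, above the highest of 0.0275 in 1000 shuffles of genes, so the chromosomes differed by more than shuffled genes. The shuffles did not keep transcript GC content, which the log2 fold changes of this comparison followed (Spearman rho 0.215). Copy number or another regional difference between the lines may contribute, and the shuffles cannot tell it apart from regional regulation or a GC trend.

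The non-coding gene Gm42418, which overlaps ribosomal RNA sequence, measured 26488 CPM in untreated B16 replicate 1 and 51.7 to 232 CPM in the other libraries, and was picked after its values were seen. The same library stands apart in GC content and replicate spread and enters every comparison with untreated B16, IFNy-treated and 499 alike.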
